A study of Mus musculus with 14 samples.

How the data were processed

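Total RNA from mouse T cells polarised to Th1 or Th2 for 2 weeks was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The data hold 14 arrays, 1 for each of 14 conditions, which are the 2 cell types in 7 treatments. The treatments were none, Thy1 siRNA, Trpm4 siRNA, an empty retroviral vector at 4 h and 12 h, and a retrovirus with dominant negative (DN) Trpm4 at 4 h and 12 h. The deposited values are probe set signal, an intensity on a linear scale. How the authors summarised probes and scaled the arrays is not given in the sources used here. Totals, medians and trimmed means (95.7 to 143.1) differed between arrays, so no common scale was assumed.

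The table had 45101 probe sets, of which 34958 were listed with 1 gene, 932 with several and 9211 with none, for 18194 genes in all. Symbols were looked up through their Entrez identifiers, which were in the gene table for 34754 probe sets and changed 0 symbols. The 64 control probe sets were left out of the tests and used to read the ratio of 3′ to 5′ signal. Signals were quantile normalised over the 14 arrays and taken as log2 of the value plus 16, which puts the floor at 4.0 and the median signal of 25.95 at 5.39. A probe set was kept when it exceeded the median of the array in at least 2 of the 14 arrays, which left 29467 probe sets and 13118 genes. Values near the floor understate differences, so signal over background limits low transcripts.

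Each comparison was fitted per probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the matched pair of arrays as a fixed block. Tests were two-sided and the Benjamini-Hochberg adjusted p had to be under 0.05. The paired fits had 6 residual degrees of freedom for Th1 minus Th2 (7 pairs), 5 for Trpm4 inhibited minus control over both cell types and 4 with a coefficient per cell type (6 pairs). They had 3 for DN Trpm4 minus vector and for 12 h minus 4 h, 2 for the differences of those effects between cell types (4 pairs), and 1 for Trpm4 siRNA minus Thy1 siRNA (2 pairs). The fits over several cell types, times or methods count real differences between these as spread. Single pairs and the correlation of pairs across probe sets were described with no test.

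The comparisons, tests, gene lists, rule for named genes and most alternatives were set before the data were examined. The rule took the 12 probe sets with the largest change in each direction among those that passed and went the same way in every pair, 1 per gene symbol. Where fewer passed, up to 6 in that direction with the highest test statistic and the same direction in every pair were named as values that did not pass. Trpm4, Thy1 and up to 6 members per list were added. Of single pairs the rule took the 6 highest and 6 lowest ratios among probe sets above the median of both arrays.

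The 20 gene lists, each with the probe set of highest mean per gene, were Th1-associated, Th2-associated, cytokine and chemokine, T cell activation and NFAT-induced, calcium signalling, migration, adhesion and actin, cell cycle, interferon response, apoptosis, unfolded protein and heat shock, glycolysis and hypoxia, cholesterol synthesis, ribosome biogenesis and sex-linked genes, and markers of B cells, macrophages and dendritic cells, CD8 T cells and natural killer cells, Treg and Th17 cells, erythroid cells and fibroblasts. They were tested with camera at a preset correlation of 0.01 and with an estimated one, and adjusted over the 20 lists of a comparison. The cytokine list shares Ifng, Il2, Tnf, Lta, Xcl1 and other genes with the Th1 list and Il4, Il5, Il10 and other genes with the Th2 list. In the glycolysis and hypoxia list the entry Gpi1 was read on a probe set of Pigq. So 1 of its 20 tested members is not a glycolysis gene. In single pairs each list median was set against 10000 random lists drawn from 20 bins of expression.

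Alternatives were the deposited and the median-centred values, no filter, a filter at the 75th percentile (15504 probe sets), eBayes with a trend or robust, 1 probe set per gene, no pair block, array weights, pseudocounts of 1 and 64, and each pair left out in turn. All 14 arrays in 1 fit were also tried for Trpm4, and 1.5-fold and 3-fold limits for single pairs. Subsets of arrays by 3′ bias, the averages of the arrays of each cell type and set, and the swaps of whole sets were chosen after seeing the data. The fits were tested on simulated data with 200 of 29467 probe sets changed by 1.5-fold, 2-fold or 4-fold. Each planted change was equal in all pairs it concerned, with independent noise. It was planted at its full size on the log2 scale, at low signals too. A real change of that fold gives a smaller log2 ratio there, so recovery of real folds at low signal is overstated. With the spread of each probe set as estimated, 169 of 365 calls in the siRNA comparison were unchanged probe sets. A simulation with the variance prior of the fit, added after that, gave 7 of 94, and its recovery is the one quoted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the values and figures.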

Results

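Transcript levels were measured on mouse Affymetrix arrays in Th1 and Th2 cells, the helper T cells that make interferon gamma and interleukin 4 respectively. The series asks how gene expression changes in each cell type when Trpm4, a calcium-activated cation channel of the plasma membrane, is inhibited. Each of 14 conditions was measured on 1 array. In each cell type the conditions were untreated cells, Thy1 siRNA, Trpm4 siRNA, an empty retroviral vector at 4 h and at 12 h, and a retrovirus carrying a dominant negative (DN) form of Trpm4 at 4 h and at 12 h. The labels do not say from which event the times were counted. With 1 array per condition there were no replicates, so matched pairs of arrays stood in for replicates in every test. Arrays of the same cell type and set, siRNA or retrovirus at one time, correlated at 0.987 to 0.996, so pairs of one set in Th1 minus Th2, and vector and DN Trpm4 pairs in 12 h minus 4 h, are not independent. The p-values therefore measure the spread between these samples alone, and the number of arrays limits the precision of every value. Total signal per array ran from 7324678 to 10608719 and the median signal from 19.88 to 28.3. Errors given after ± are standard errors from the limma fit on the log2 scale, with the number of pairs as n.

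The targeted genes were read first, each on its single probe set. Trpm4 had a deposited signal of 100.3 with Thy1 siRNA and 58.44 with Trpm4 siRNA in Th1 cells. In Th2 cells the deposited Trpm4 signals were 133.38 and 84.47. The log2 ratios of the siRNA pairs were -0.72 in Th1 and -0.63 in Th2, a mean of -0.68 ± 0.10 (2 pairs) that did not pass (adjusted p = 0.409, limma). Under the DN retrovirus the deposited Trpm4 signal in Th1 cells at 12 h was 515.59, against 75.31 with the vector. On the normalised log2 scale, used for all ratios here, the values were 9.21 and 6.62, a ratio of 2.59. The log2 ratio of DN Trpm4 over vector was 0.60 in Th1 at 4 h, -0.21 in Th2 at 12 h and 0.09 in Th2 at 4 h. Whether this probe set detects the DN construct is unknown. The 4 DN pairs gave a mean of 0.77 ± 0.35 that did not pass (adjusted p = 1). In untreated cells the deposited Trpm4 signal was 76.41 in Th1 and 160.74 in Th2, and after normalisation 103.7 and 176.3. Thy1, a glycoprotein of the T cell surface, had log2 signals of 11.12 in Th1 and 9.61 in Th2 with Thy1 siRNA, against 12.46 and 11.71 with Trpm4 siRNA. Its mean ratio of Trpm4 siRNA over Thy1 siRNA was 1.72 ± 0.20 on the log2 scale (2 pairs, adjusted p = 0.409), so the gene behind that siRNA differed between the arms of every siRNA pair.

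**Figure D1:**
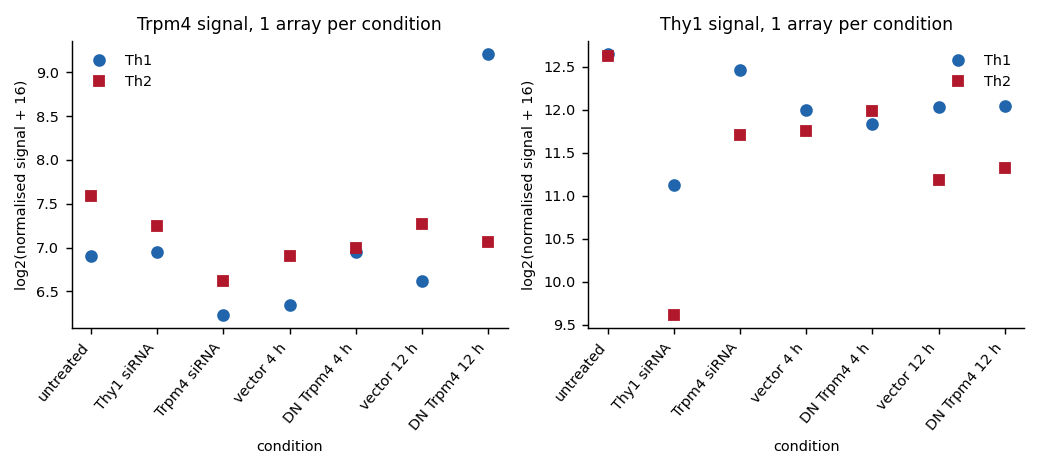
Signal of Trpm4 (left) and Thy1 (right), as log2 of the normalised signal plus 16, for the 7 conditions on the x axis, with Th1 as blue circles and Th2 as red squares and 1 array per point. Trpm4 reached 9.21 in Th1 cells with DN Trpm4 at 12 h, and Thy1 was lowest in both cell types with Thy1 siRNA, at 11.12 and 9.61.

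Control probe sets showed that the arrays fell into 2 kinds. In 6 arrays, the Th1 pair at 4 h and the Th2 pairs at 4 h and 12 h, the 3′ probe set of Gapdh exceeded the 5′ probe set by 5.43 to 5.91 on the log2 scale and that of Actb by 3.96 to 4.85. In the other 8 arrays the same ratios ran from -0.25 to 0.04 for Gapdh and from 0.05 to 0.47 for Actb. The ratio of Tfrc, a weaker transcript, overlapped between the kinds, at 2.13 to 3.09 and 1.47 to 2.91. Both arrays of each Trpm4 pair were of one kind, but not equal in bias. In the Th2 pair at 4 h the Actb ratio was 3.96 with the vector and 4.85 with DN Trpm4, and the Tfrc ratio 2.46 and 3.09. The Th1 arrays at 12 h lacked this 3′ bias and the Th2 arrays at 12 h had it, so the kind of array differed between cell types at 12 h and between times in Th1 cells.

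**Figure D2:**
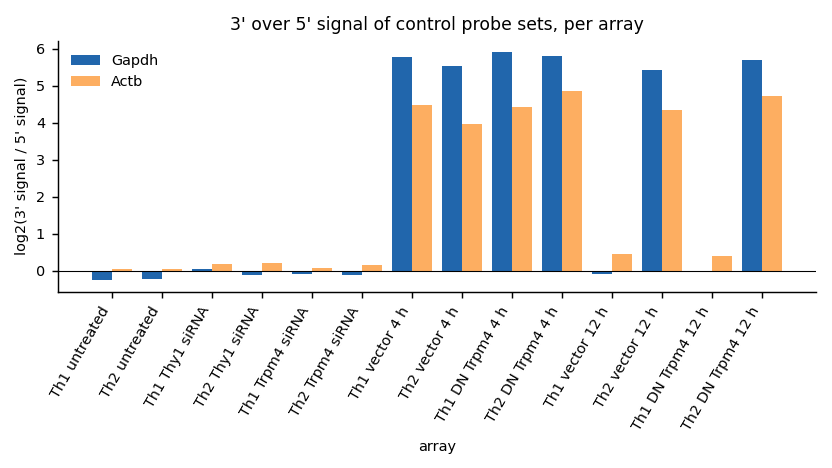
Log2 ratio of 3′ over 5′ signal of the control probe sets of Gapdh (blue) and Actb (orange) on the y axis, for each of the 14 arrays on the x axis. The 6 retrovirus arrays with bias stand between 5.43 and 5.91 for Gapdh, while the other 8 arrays stay at or below 0.04.

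The main question of the series was what inhibition of Trpm4, by siRNA or DN retrovirus, changed in both cell types. No named gene rose or fell by the test across the 6 pairs. The genes nearest to passing that went the same way in all 6 pairs were small in effect. Prss12, a serine protease, had a log2 ratio of 0.32 ± 0.07 (6 pairs), and Clec11a, a secreted growth factor of the C-type lectin family, one of 0.30. Lower values were seen for Gpat3, an acyltransferase of triglyceride synthesis, at -0.59 ± 0.13, for Crx, a transcription factor of photoreceptors, at -0.41 ± 0.08, and for Ackr1, a chemokine receptor that does not signal, at -0.33 (adjusted p = 0.809 for each). The signal of Crx was low, with mean log2 values of 5.15 inhibited and 5.56 in controls, close to the median signal of 5.39. Limma called 0 of 29467 probe sets, against 1733 at an unadjusted p under 0.05 where chance gives 1473, and 0 under every other setting run for this comparison. None of the 20 gene lists passed, the smallest adjusted p being 0.121 for cell cycle genes (median -0.05). Adjusted over the list alone, 0 members passed in 19 lists and 1 in the markers of B cells. In simulated data of this design with the variance prior of the fit, 82.1% of 1.5-fold changes and 100% of 2-fold changes were recovered. The planted changes were equal in all pairs, so these shares do not cover a change with 1 method, time or cell type alone. They were planted at full size on the log2 scale, with median log2 ratios of 0.57 at 1.5-fold and 1.01 at 2-fold. Near the floor a real change of that fold gives a smaller log2 ratio. The simulated recovery, here and in the comparisons below, therefore overstates that of real folds at low signal.

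In Th1 cells, cell cycle genes were lower as a group with Trpm4 inhibited. The list had a median log2 ratio of -0.15 over 34 genes (mean -0.15), and 1 member, the thymidylate synthase gene Tyms, lay above 0 at 0.14. Among the lowest were Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at -0.33 ± 0.12, and the proliferation marker Mki67 at -0.33 ± 0.10. The centromeric histone gene Cenpa stood at -0.28, the mitotic kinase gene Plk1 at -0.27 and the cyclin genes Ccne1 and Ccna2 at -0.25 and -0.22 (3 pairs, adjusted p = 1 for each). The list passed in camera with an adjusted p of 4.88e-10, and with an adjusted p of 0.0306 with an estimated correlation. That estimate was -0.0098, under the preset 0.01, so it was no stricter check on genes that move together. No member passed singly, over all genes or adjusted over the list alone. The median was negative in each of the 3 Th1 pairs, at -0.10 with siRNA, -0.16 with DN Trpm4 at 4 h and -0.13 with DN Trpm4 at 12 h. Other values nearest to passing in Th1 were Nedd4l, a ubiquitin ligase, at 0.41, Mtus1 at -0.51, Nmnat3, an enzyme of NAD synthesis, at -0.50 and Evc2 at -0.87 ± 0.20 (adjusted p = 1 for each). Nedd4l and Nmnat3 each have another probe set of opposite sign. With and without Trpm4 inhibited, the mean log2 signals were 4.34 and 5.21 for Evc2 and 5.23 and 4.82 for Nedd4l. These lie below the median signal of 5.39, near the floor of 4.0. Limma called 0 probe sets, against 928 at an unadjusted p under 0.05, fewer than the 1473 that chance gives. It called 0 under every other setting run. The simulated recovery was 26.9% at 1.5-fold and 92.5% at 2-fold.

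In Th2 cells no list and no gene passed. Cell cycle genes had a median of 0.02 (adjusted p = 0.361), cytokine and chemokine genes one of -0.14 (adjusted p = 0.0686) and T cell activation genes one of -0.09 (adjusted p = 0.0744). The values nearest to passing were those of Ccdc173 at 0.79 ± 0.16, Rassf6 at 0.54, Extl2 at -0.48 and Uhrf2, a chromatin-binding ubiquitin ligase, at -1.38 ± 0.26 (3 pairs, adjusted p = 0.768 for each). Uhrf2 ran from -2.33 to -0.44 over the pairs, and its other probe set stood at 0.16. The other probe set of Extl2 stood at 0.03. Limma called 0 probe sets, against 1824 at an unadjusted p under 0.05 where chance gives 1473, and 0 under every other setting run. The simulated recovery was 34.3% at 1.5-fold and 92.5% at 2-fold.

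The effects of Trpm4 inhibition in the cell types were then compared by a test of their difference, Th1 effect minus Th2 effect. Cell cycle genes differed, with a median of -0.24 and an adjusted p of 5.84e-08 in camera. With an estimated correlation, here -0.0098, the adjusted p was 0.0476. The Th2 siRNA pair, where the list median was 0.07, adds to this difference. Cytokine and chemokine genes stood higher in the Th1 effect, with a median of 0.17 (adjusted p = 0.00977, and adjusted p = 0.974 with an estimated correlation). Th2-associated genes had a median of 0.14 (adjusted p = 0.0424, and adjusted p = 0.974 with an estimated correlation). Without the Th2 pair of DN Trpm4 at 4 h the cytokine median was -0.03 and that of the Th2-associated genes 0.03 (adjusted p = 0.982). Leaving out the Th1 siRNA pair also ended the cytokine call (0.12, adjusted p = 0.141). Leaving out the Th1 pair of DN Trpm4 at 12 h or at 4 h ended the call of the Th2-associated genes (0.15, adjusted p = 0.0979, and 0.18, adjusted p = 0.171). Over the alternatives the adjusted p ran from 1.22e-05 to 0.974 for cytokine genes and from 7.74e-05 to 0.982 for Th2-associated genes. No single gene passed, with Uhrf2 at 1.51 ± 0.37 (0.10 on its other probe set), the acute phase gene Saa3 at 1.03 and Rassf6 at -0.83 (6 pairs, adjusted p = 1 for each). Limma called 0 probe sets, against 1032 at an unadjusted p under 0.05, fewer than the 1473 that chance gives. It called 0 under every other setting run, with a simulated recovery of 3% at 1.5-fold and 53.7% at 2-fold.

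**Figure D3:**
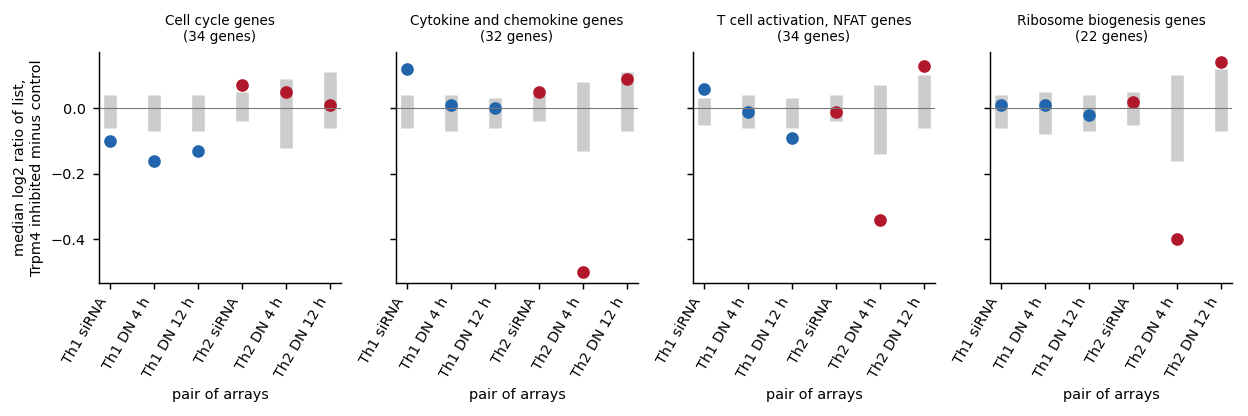
Median log2 ratio of 4 gene lists on the y axis, Trpm4 inhibited minus control, in each of the 6 pairs of arrays on the x axis (Th1 blue, Th2 red), with grey bars for the central 95% of 10000 random lists of matched expression. Cell cycle genes lie below the bars in the 3 Th1 pairs, and cytokine, activation and ribosome biogenesis genes lie below them in the Th2 pair at 4 h, at -0.50, -0.34 and -0.40. Activation genes also lie below them in the Th1 pair of DN Trpm4 at 12 h (-0.09). Above the bars lie cell cycle genes in the Th2 siRNA pair (0.07), cytokine genes in both siRNA pairs (0.12 in Th1, 0.05 in Th2), activation genes in the Th1 siRNA pair (0.06) and activation and ribosome biogenesis genes in the Th2 pair at 12 h (0.13 and 0.14).

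With the retrovirus alone, DN Trpm4 was compared with the vector in 4 pairs. T cell activation and NFAT-induced genes had a lower median of -0.07 (adjusted p = 0.00319), cytokine and chemokine genes one of -0.10 (adjusted p = 0.0115) and cell cycle genes one of -0.05 (adjusted p = 0.0175). Each of these 3 had an adjusted p of 0.854 with an estimated correlation. Without the Th2 pair at 4 h the activation median was 0.02 and the cytokine median 0.04. Leaving out the Th1 pair at 12 h or at 4 h ended the cell cycle call (adjusted p = 0.449 and 0.498, from 5.2e-04 to 0.854 over the alternatives). The values nearest to passing were those of Hrct1 at 0.40, the collagen-modifying hydroxylase P3h3 at 0.72, Crx at -0.52 ± 0.09, the Notch target Nrarp at -0.44 and the myeloid transcription factor Spi1 at -0.38 (adjusted p = 1 for each). Mean log2 signals with DN Trpm4 and vector were 5.2 and 4.8 for Hrct1, 5.29 and 4.57 for P3h3 and 4.87 and 5.3 for Nrarp. All of these lie below the median signal of 5.39. Limma called 0 probe sets, against 997 at an unadjusted p under 0.05, fewer than the 1473 that chance gives. It called 0 under every other setting run, with a simulated recovery of 50.7% at 1.5-fold and 98.5% at 2-fold.

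The difference of the DN Trpm4 effect between Th1 and Th2 cells had list medians of -0.20 for cell cycle genes (adjusted p = 1.59e-04), 0.23 for cytokine and chemokine genes (adjusted p = 0.00649) and 0.20 for Th2-associated genes (adjusted p = 0.0272). With an estimated correlation the adjusted p was 0.713 for cell cycle genes and 0.923 for the other lists. Without the Th2 pair at 4 h the cytokine median and that of the Th2-associated genes were each -0.06, and without the Th1 pair at 4 h both calls ended (adjusted p = 0.0744 and 0.107, with a highest value of 0.923 and lowest values of 1.17e-10 and 3.51e-07 over the alternatives). Single genes did not pass, with Uhrf2 at 1.93 ± 0.31 (0.15 on its other probe set), the growth factor gene Mdk at 1.13, Tpbg at 0.88 and Lix1l at -0.87 (adjusted p = 1 for each). Limma called 0 probe sets, against 976 at an unadjusted p under 0.05, fewer than the 1473 that chance gives. The count was 1 without the Th2 pair at 12 h and 0 under the other settings run, and the simulated recovery was 4.5% at 2-fold and 93.9% at 4-fold.

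Trpm4 siRNA was compared with Thy1 siRNA in 2 pairs, 1 per cell type, which left 1 residual degree of freedom. Glycolysis and hypoxia genes were higher as a group, with a median of 0.16 and 18 of 20 members above 0 (adjusted p = 0.0115, and adjusted p = 0.956 with an estimated correlation). The Th1 pair carried this, with a median of 0.23 against 0.04 in Th2, which lay within the central range of random lists (-0.05 to 0.05). Among the 20 members Pigq stood in the place of the glycolysis gene Gpi1. Next to Thy1 and Trpm4 themselves, the values nearest to passing were those of Samd10 at 0.88 ± 0.12, Rps6kc1 at 0.71, Ccdc191 at -1.49 ± 0.15, the endothelin gene Edn3 at -1.12 ± 0.11, Pbp2 at -1.27 and Gpat3 at -0.89 ± 0.11 (2 pairs, adjusted p = 0.409 for each). Edn3 has another probe set of opposite sign. With Trpm4 siRNA the mean log2 signals of Ccdc191 and Pbp2 were 4.38 and 4.55, close to the floor of 4.0. Limma called 0 probe sets, against 3318 at an unadjusted p under 0.05 where chance gives 1473. With a variance trend in limma the count was 98, of which 32 were higher and 66 lower. Trpm4 passed under that setting (adjusted p = 0.0232), and its adjusted p ran from 0.0232 to 1 over the alternatives, and that of Thy1 from 9.36e-08 to 1. With a pseudocount of 64 the count was 4, with Thy1 and Edn3 among them, and under the other settings run it was 0. The simulated recovery was 32.8% at 2-fold and 98.5% at 4-fold. Adjusted over the list alone, 1 macrophage and dendritic cell marker and 1 fibroblast marker were lower and no member of the other lists passed. In the comparisons of Th1, of Th2, of DN Trpm4 and of both differences, 0 members of any list passed adjusted over the list alone. Median, mean and test differed in sign for some lists that did not pass. In the comparison over both cell types these were interferon response and sex-linked genes, and in Th1 they were Th1-associated and interferon response genes and CD8 T cell and natural killer cell markers. In the difference between cell types they were calcium signalling, interferon response and apoptosis genes and fibroblast markers. With DN Trpm4 they were fibroblast markers, in the DN Trpm4 difference calcium signalling and apoptosis genes and the markers of macrophages and of Treg and Th17 cells, and with siRNA interferon response genes. Of the list calls with Trpm4 inhibited, those of cell cycle genes in Th1 and in the difference between cell types held with an estimated correlation. The estimate behind both was -0.0098, which makes no allowance for genes moving together. In the fit over both cell types it was 0.205 for this list.

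Log2 ratios of the pairs with Trpm4 inhibited were weakly related across genes. Over the 15 combinations of 2 pairs, which had no array in common, Pearson's r of the log2 ratios across 29467 probe sets had a median of -0.01 and ran from -0.13 to 0.23, and Spearman's rho from -0.12 to 0.23. The highest value was that of the siRNA pairs in Th1 and Th2. Probe sets are not independent replicates, so these values are descriptive.

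Th1 and Th2 cells were compared in 7 pairs of arrays with the same treatment and time. Th2 cells had higher transcripts of the type 2 cytokines Il4 and Il5, at log2 differences of Th1 minus Th2 of -6.59 ± 0.52 (adjusted p = 8.87e-05) and -5.68 ± 0.56 (adjusted p = 3.66e-04). The lowest value in Th1 was that of Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, with a mean log2 signal of 5.07 in Th1 and 11.76 in Th2, a difference of -6.69 ± 0.17 (adjusted p = 1.09e-07). Th1 cells had higher transcripts of Klrc1 and Klrd1, which form an inhibitory receptor of natural killer cells, at 5.35 ± 0.26 and 5.03 ± 0.39. They were also higher for Lta, which encodes lymphotoxin alpha, at 5.27 ± 0.42 (adjusted p = 8.87e-05), and for the T cell growth factor Il2 at 3.84 ± 0.47 (adjusted p = 0.00121).

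**Figure D4:**
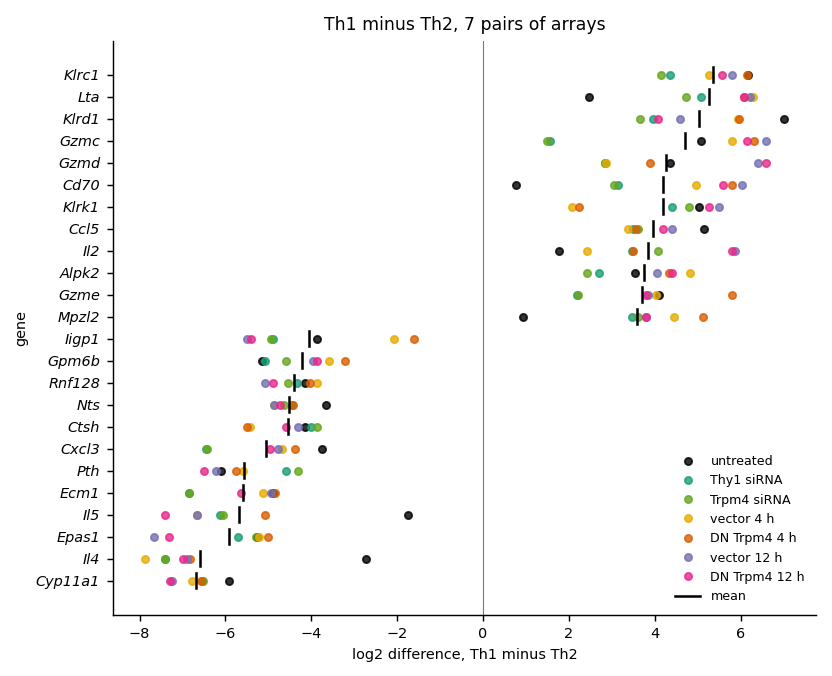
Log2 difference of Th1 minus Th2 on the x axis for the 24 named genes on the y axis, with 1 coloured point for each of the 7 pairs and a black bar for the mean. Differences ran from -6.69 for Cyp11a1 to 5.35 for Klrc1, and the untreated pair (black points) gave the smallest difference of the 7 for Il4, Il5 and Lta.

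Further genes higher in Th1 were those of some granzymes, proteases of cytotoxic granules, namely Gzmc at 4.71 ± 0.66, Gzmd at 4.25 ± 0.50 and Gzme at 3.70 ± 0.38. These granzyme genes and Klrc1 have closely similar relatives, so which member gave the signal is uncertain. The TNF family ligand Cd70 stood at 4.20 ± 0.58, the activating receptor gene Klrk1 at 4.18 ± 0.43, the chemokine gene Ccl5 at 3.97 ± 0.22, the kinase gene Alpk2 at 3.75 ± 0.28 and the adhesion gene Mpzl2 at 3.59 ± 0.40. Further genes lower in Th1 were Epas1, a hypoxia-inducible transcription factor, at -5.93 ± 0.34, the matrix protein gene Ecm1 at -5.59 ± 0.28, the parathyroid hormone gene Pth at -5.58 ± 0.27 and the chemokine gene Cxcl3 at -5.06 ± 0.32. The lysosomal protease gene Ctsh stood at -4.55 ± 0.22, the neurotensin gene Nts at -4.52 ± 0.16, the ubiquitin ligase gene Rnf128 at -4.41 ± 0.17, Gpm6b at -4.21 ± 0.24 and the interferon-inducible GTPase gene Iigp1 at -4.05 ± 0.48. The adjusted p of these 17 genes was 0.00266 or lower. Trpm4 (-0.07 ± 0.31, adjusted p = 0.912) and Thy1 (0.57 ± 0.19, adjusted p = 0.0961) did not pass. Trpm4 stood at 2.16 in the DN Trpm4 pair at 12 h and between -0.68 and -0.05 in the other 6 pairs, and without that pair its mean was -0.44 (adjusted p = 0.104, from 0.104 to 0.993 over the alternatives). Thy1 passed on the median-centred values (0.76, adjusted p = 0.0424, from 0.0424 to 0.845 over the alternatives). It was highest in the Thy1 siRNA pair, at 1.52, where Thy1 itself was targeted. In the other 6 pairs Thy1 ran from -0.15 to 0.84, with 0.03 in the untreated pair.

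Of 24 Th1-associated genes, 13 were higher and 1 lower in Th1 cells, and 15 and 1 adjusted over the list alone (median 1.07, adjusted p = 1.24e-09, and adjusted p = 0.115 with an estimated correlation). Ifng stood at 3.54 ± 0.27, the receptor genes Il18r1 and Il12rb2 at 3.0 ± 0.22 and 2.51 ± 0.37, the chemokine gene Xcl1 at 2.74 ± 0.51 and Stat4, which relays interleukin 12 signals, at 1.17 ± 0.20. The lower member was the receptor gene Il12rb1 at -1.56 ± 0.12. Of 22 Th2-associated genes, 14 were lower and 0 higher in Th1 cells in limma, and 15 and 2 adjusted over the list alone (median -2.09, adjusted p = 3.05e-12, and adjusted p = 0.0127 with an estimated correlation). The transcription factor genes Maf and Gata3 stood at -3.69 ± 0.30 and -2.92 ± 0.12, Il13 at -3.59 ± 0.38 and Il10 at -2.55 ± 0.34. Of 32 cytokine and chemokine genes, 11 were higher and 8 lower, and 17 and 8 adjusted over the list alone (median 0.88, adjusted p = 0.0376, and adjusted p = 0.448 with an estimated correlation). Members that no other list holds were Csf2 at 1.37 ± 0.13, Lif at -2.69 and Il21 at -1.88 ± 0.31. Without the 12 h pairs the cytokine call ended (0.37, adjusted p = 0.185). It also ended without the vector or the DN Trpm4 pair at 12 h (0.69, adjusted p = 0.0531 and 0.0506) or without the DN Trpm4 pair at 4 h (0.91, adjusted p = 0.0631), with adjusted p values from 0.00371 to 0.762 over the alternatives.

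Of 22 ribosome biogenesis genes, 11 were higher in Th1 cells and 0 lower, and 15 and 0 adjusted over the list alone (median 0.57, adjusted p = 2.04e-08, and adjusted p = 0.154 with an estimated correlation), with the nucleolin gene Ncl at 0.97 ± 0.16. Of 25 interferon response genes, 0 were higher and 11 lower, and 0 and 16 adjusted over the list alone (median -0.74, adjusted p = 5.32e-07, and adjusted p = 0.126 with an estimated correlation). Irf1 stood at -2.03 ± 0.37, Xaf1 at -1.33 ± 0.12 and the nucleic acid sensor gene Zbp1 at -1.23. Of 34 cell cycle genes, 2 were lower, here and adjusted over the list alone, the replication genes Cdt1 at -0.78 ± 0.16 and Mcm2 at -0.75 (median -0.55, adjusted p = 0.00163, and adjusted p = 0.875 with an estimated correlation). In the untreated and siRNA pairs alone the cell cycle median was 0.67 (adjusted p = 0.00161), made of 1.32 and 0.95 in the Thy1 and Trpm4 siRNA pairs and -0.51 in the untreated pair. In the retrovirus pairs it ran from -1.63 to -0.92. Without the vector or the DN Trpm4 pair at 4 h the call over all pairs ended (-0.39, adjusted p = 0.0518, and -0.35, adjusted p = 0.0631). Over the alternatives the adjusted p ran from 1.37e-27 to 0.875.

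T cell activation genes had 4 higher and 4 lower members of 34, and 5 and 4 adjusted over the list alone (adjusted p = 0.931), among them Myc at 1.56 ± 0.19 and Fos at -2.03 ± 0.31. Migration, adhesion and actin genes had 2 higher and 6 lower members of 34, and 3 and 6 adjusted over the list alone (adjusted p = 0.726). Among these were the integrin genes Itgb1 at 1.45 ± 0.16 and Itgae at -2.60 ± 0.51. Of 40 calcium signalling components 2 were lower, the inositol trisphosphate receptor gene Itpr2 at -1.59 ± 0.32 and the mitochondrial calcium channel gene Mcu at -1.04 ± 0.24, and 12 were lower and 2 higher adjusted over the list alone (median -0.12, adjusted p = 0.0568). Without the 12 h pairs this list passed (-0.20, adjusted p = 0.0114, and adjusted p = 0.38 with an estimated correlation). Glycolysis and hypoxia genes (1 higher, 2 lower of 20, Ero1a at -2.18 ± 0.18), unfolded protein and heat shock genes (3 higher, 2 lower of 22) and apoptosis genes (1 lower of 21, Mcl1 at -0.71) had adjusted p values of 0.931, 0.848 and 0.848. Cholesterol synthesis genes had 1 higher and 1 lower member of 16 (adjusted p = 0.241). Adjusted over the list alone, the counts of these 4 lists were the same.

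Markers of other cell types moved with the cell type as well. Of 7 markers of CD8 T cells and natural killer cells 4 were higher in Th1, Klrd1, Klrk1, Klre1 at 0.76 and the perforin gene Prf1 at 2.79 ± 0.21, with 4 higher and 1 lower adjusted over the list alone (median 0.76, adjusted p = 0.00163, and adjusted p = 0.115 with an estimated correlation). Of 14 markers of macrophages and dendritic cells 1 was lower, the lectin receptor gene Clec7a at -2.45 ± 0.20, with 4 lower adjusted over the list alone (median -0.35, adjusted p = 0.00704, and adjusted p = 0.196 with an estimated correlation). In the 4 h pairs alone that call ended (-0.06, adjusted p = 0.226, from 0.00174 to 0.226 over the alternatives). B cell markers (1 of 8 higher, Ebf1 at 2.16; median -0.22 but mean 0.12, adjusted p = 0.932) and markers of Treg and Th17 cells (Ikzf2 of 4 higher at 1.65 and 1 lower, adjusted p = 0.931) did not pass as lists. Nor did markers of fibroblasts (Fn1 of 6 lower at -0.88, adjusted p = 0.931), erythroid cells (0 of 2 in limma, median -0.11, adjusted p = 0.931) or sex-linked genes (0 of 4 in limma, median 0.55, adjusted p = 0.76). Adjusted over the list alone, 1 B cell marker was higher, 1 Treg and Th17 marker higher and 2 lower, and 1 fibroblast marker higher and 1 lower, while no erythroid or sex-linked gene passed. The sex-linked list joins Xist with genes of the Y chromosome, which go opposite ways between the sexes. Their signs can cancel in its mean and list test. In 2 of the 7 pairs all 4 sex-linked genes differed at least 2-fold, so the cells of these pairs were not matched in everything but cell type, and any difference between their sources is part of the values. Of the list calls for Th1 minus Th2, that of the Th2-associated genes held with an estimated correlation and the other 7 did not.

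In limma 2884 of 29467 probe sets passed, 1076 higher and 1808 lower in Th1 (781 and 1206 genes), of which 1088 differed at least 2-fold and 2460 went the same way in all 7 pairs. With the arrays of each set averaged, which leaves 4 pairs, 271 passed (3849 at an unadjusted p under 0.05), all of them among the 2884. Of the 24 named genes Cd70 and Mpzl2 no longer passed there (adjusted p = 0.0918 and 0.0513). Without the 12 h pairs, whose arrays differed in 3′ bias, 1256 probe sets passed and 1081 of them were among the 2884. Leaving out the Thy1 siRNA pair, the Trpm4 siRNA pair, the vector pair at 12 h, the DN Trpm4 pair at 12 h or the DN Trpm4 pair at 4 h gave 1907, 1802, 1509, 1450 and 1770. In the untreated and siRNA pairs alone the count was 319, and Lta, Klrd1, Gzmc, Cd70, Il2, Gzme, Mpzl2, Il4 and Il5 no longer passed (adjusted p from 0.0661 to 0.192).

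The 12 h arrays were compared with the 4 h arrays in 4 pairs of the same cell type and virus. At 12 h the replication licensing gene Cdc6 was higher by 2.20 ± 0.12 on the log2 scale (adjusted p = 0.0313, 2.14 to 2.28 over the pairs), and with it the replication fork gene Timeless at 2.06 ± 0.34 and the chromatin remodelling gene Hells at 1.85 ± 0.19. The disulfide isomerase gene Pdia5 was higher at 2.34 ± 0.25, the cargo receptor gene Lman1 at 1.96 and Sdf2l1 at 1.83 ± 0.28. The immediate early gene Fos was lower at -2.85 ± 0.40 (adjusted p = 0.0403), as were the cytokine gene Il21 at -2.59 ± 0.30 (adjusted p = 0.0345) and the survival gene Bcl2 at -2.35 ± 0.34 (adjusted p = 0.0412). The gene with the lowest value was Tbc1d4, a regulator of vesicle traffic, at -3.49 ± 0.38 (adjusted p = 0.0337), on 1 of its 2 probe sets, the other standing at 0.15.

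Further genes higher at 12 h were Akr1c18, a steroid dehydrogenase, at 2.85 ± 0.46, Xcl1 at 2.39 ± 0.37, Npnt at 2.02, Pa2g4 at 1.98, Hivep3 at 1.97 (4 of 5 probe sets higher) and Neto2 at 1.86. Further genes lower at 12 h were the glycogen phosphorylase gene Pygl at -3.17 ± 0.42, the ganglioside synthesis gene St8sia1 at -2.74 ± 0.21, Mgst2 at -2.63, Mxd4, an antagonist of Myc, at -2.61 and Pik3ip1, an inhibitor of PI3 kinase, at -2.58. Pdcd4, an inhibitor of translation, stood at -2.39, as did Prxl2c, and the histone gene H2az2 at -2.37. The adjusted p of these 14 genes was between 0.0313 and 0.0475. Trpm4 (0.74, adjusted p = 0.25) and Thy1 (-0.24, adjusted p = 0.433) did not pass. The Trpm4 value rests on the Th1 DN Trpm4 pair at 2.27, the others being 0.27, 0.36 and 0.06, and it was 0.23 without that pair.

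**Figure D5:**
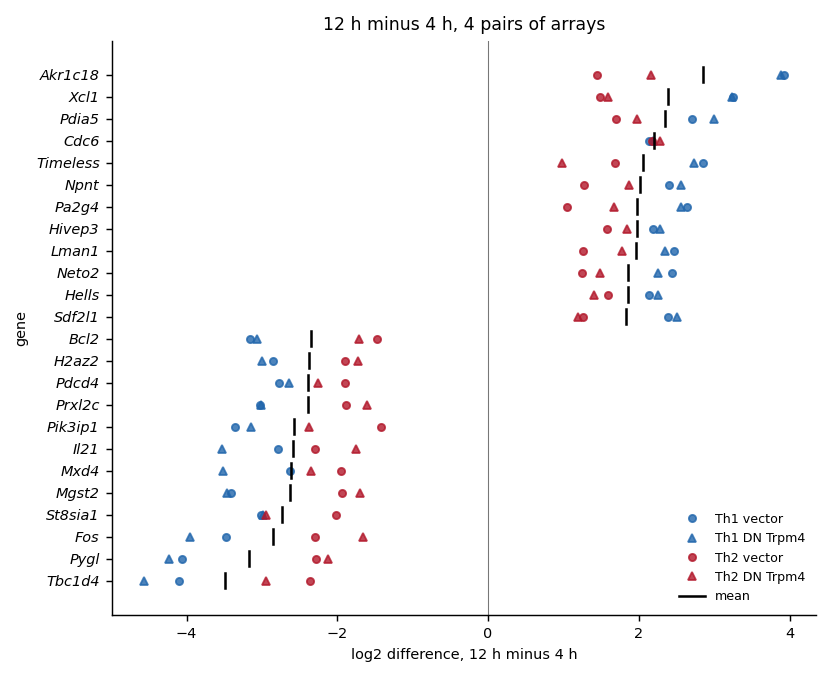
Log2 difference of 12 h minus 4 h on the x axis for the 24 named genes on the y axis, with 1 point per pair (Th1 blue, Th2 red, circles for vector and triangles for DN Trpm4) and a black bar for the mean. Differences ran from -3.49 for Tbc1d4 to 2.85 for Akr1c18, and the Th1 pairs, whose arrays differ in 3′ bias, lie farther from 0 than the Th2 pairs for most genes.

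In camera 7 lists passed at 12 h against 4 h at the preset correlation and none with an estimated correlation (adjusted p = 0.326 for each, or 0.337 for interferon response genes). Of these, cell cycle genes were higher, with 8 of 34 passing, 18 adjusted over the list alone (median 0.71, adjusted p = 1.25e-07), among them Mcm2 at 1.74 ± 0.19, Mcm5 at 1.73 and the cyclin gene Ccne2 at 1.20. Ribosome biogenesis genes were higher, with 2 of 22 passing, 13 adjusted over the list alone (median 0.60, adjusted p = 7.03e-06), the pyrimidine synthesis gene Cad at 1.47 and Nhp2 at 0.88. Unfolded protein and heat shock genes had 7 higher and 1 lower members of 22, and 9 and 2 adjusted over the list alone (median 0.39, adjusted p = 0.00128), with the chaperone genes Hsp90b1 at 1.59 ± 0.17 and Calr at 1.27 higher and Hspa1a at -1.09 lower. T cell activation and NFAT-induced genes were lower, with 7 of 34 passing, 16 adjusted over the list alone (median -0.77, adjusted p = 6.11e-06). These included Nfkbid at -1.98 ± 0.18, Nr4a3 at -1.92 ± 0.17 and Egr3 at -1.65. Interferon response genes (Mx1 of 25 passing at -1.03, 15 adjusted over the list alone, median -0.54, adjusted p = 0.00128) and migration genes (Selplg of 34 passing at -1.77, 11 adjusted over the list alone, median -0.35, adjusted p = 7.44e-04) were lower as groups. Sex-linked genes had an adjusted p of 0.0474, with 0 of 4 members passing in limma and 2 lower adjusted over the list alone (median -0.59). None of the 4 members lay above 0, so Xist and the genes of the Y chromosome moved the same way here. That call ended without the Th1 DN Trpm4 pair (-0.54, adjusted p = 0.0546), the Th2 vector pair (-0.64, adjusted p = 0.0722) or the Th2 DN Trpm4 pair (-0.58, adjusted p = 0.0827), and in the Th2 pairs alone (-0.26, adjusted p = 0.107, from 0.0445 to 0.326 over the alternatives). It ended on the deposited and the median-centred values and with the arrays averaged as well (adjusted p = 0.0611, 0.0601 and 0.0667).

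The other lists did not pass at 12 h against 4 h. Th1-associated genes had 2 higher and 3 lower members, and 7 and 11 adjusted over the list alone (adjusted p = 0.478), with Xcl1 and Ccl5 (1.48) higher and Il18r1 at -2.20 lower. Cytokine and chemokine genes had 3 higher and 3 lower members, and 8 and 7 adjusted over the list alone (adjusted p = 0.498). Calcium signalling components (Plcg1 lower at -0.86, adjusted p of the list 0.0843) and apoptosis genes (Bcl2 lower, adjusted p of the list 0.0843) had 13 lower and 2 higher and 5 lower members adjusted over the list alone. Glycolysis and hypoxia genes (Pfkl higher at 1.42, Egln3 lower at -1.29) and markers of macrophages and dendritic cells (Clec7a lower at -0.90) had adjusted p values of 0.83 and 0.478, with 4 higher and 4 lower and with 3 lower members adjusted over the list alone. Limma called 0 members of the Th2-associated (0.921), cholesterol synthesis (0.391), B cell (0.673), CD8 T cell and natural killer cell (0.85), Treg and Th17 (0.846), erythroid (0.846) and fibroblast (0.478) lists, whose adjusted p values stand in parentheses. Adjusted over the list alone 1 Th2-associated gene was lower and no member of the other 6 passed. The CD8 T cell and natural killer cell markers had a median of 0.13 and a mean of 0.08 while their test pointed down.

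In all, 592 probe sets passed for time, 210 higher and 382 lower at 12 h (165 and 291 genes), 453 of them at least 2-fold. The share that was higher was 16.6% on the deposited and 19% on the median-centred values, so the balance of directions depends on the scaling. With the vector and DN Trpm4 arrays averaged, which leaves 1 pair per cell type, limma called 0 (2188 at an unadjusted p under 0.05), and the named genes had an adjusted p of 0.623. The 2 Th2 pairs, whose 4 arrays all had 3′ bias, gave 1846 passing probe sets that held all 592, with Cdc6 at 2.23, Tbc1d4 at -2.65, Fos at -1.97, Il21 at -2.03 and Bcl2 at -1.60. These 2 pairs are part of the data behind the 592, so the overlap is no independent support. They left 1 residual degree of freedom and are close to duplicates, so their spread is a low estimate. In those pairs cell cycle (0.30, adjusted p = 6.7e-08), ribosome biogenesis (0.57, adjusted p = 5.3e-09) and unfolded protein genes (0.48, adjusted p = 2.55e-06) were again higher, and activation genes (-0.52, adjusted p = 2e-10) lower, each with an adjusted p of 0.674 with an estimated correlation. Of 34 cell cycle genes 13 passed there, all higher, among them Mcm2 at 1.39 and Ccne1 at 1.10. Others did not rise, such as Mki67 at -0.22, Ccnb2 at -0.54 and Aurkb at -0.02. Without any one of the 4 pairs, or with a pseudocount of 1, the count over both cell types was 0 in limma (3874 to 9656 and 7978 at an unadjusted p under 0.05). On the deposited or the median-centred values Akr1c18, Xcl1, Timeless, Pa2g4 and Sdf2l1 did not pass (adjusted p from 0.0501 to 0.0576).

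The change between the times differed between Th1 and Th2 cells for 11253 probe sets, 5340 higher and 5913 lower in the Th1 effect. The highest value was that of Ube2s, a ubiquitin-conjugating enzyme gene, at 5.39 ± 0.24 (5.72 in Th1, 0.34 in Th2, adjusted p = 1.35e-05). The lowest was that of Gbp6, a GTPase gene of the interferon response, at -3.87 ± 0.20 (-4.40 in Th1, -0.54 in Th2, adjusted p = 2.27e-05). Interferon-inducible GTPase genes among the named ones were also Irgm2 at -3.67, Iigp1 at -3.61 and Igtp at -3.34, and the cholesterol synthesis gene Cyp51 stood at -3.30. The interferon response list did not pass in camera (4 higher and 8 lower of 25, median -0.34, adjusted p = 0.164). Cell cycle genes differed as a list (15 higher and 2 lower of 34, also adjusted over the list alone; median 0.44, adjusted p = 0.00364, and adjusted p = 0.879 with an estimated correlation), with Ube2c at 2.08 and Birc5 at -1.24. Cholesterol synthesis genes did so too (2 higher and 9 lower of 16, also adjusted over the list alone; median -1.0, adjusted p = 0.0211, and adjusted p = 0.879 with an estimated correlation), with Idi1 at -2.03 and Hmgcs1 at -1.96. The cholesterol call ended without the Th2 DN Trpm4 pair (-1.05, adjusted p = 0.0522, from 0.0116 to 0.879 over the alternatives). Median and test differed in sign for Th1-associated and unfolded protein genes, which did not pass. In both Th1 pairs the kind of array changed with time and in the Th2 pairs it did not, so cell type and kind of array cannot be told apart in this difference. The 2 pairs of each cell type are close to duplicates, so the spread in this test is a low estimate, and with the arrays averaged no residual degrees of freedom were left for it. Within the 2010 genes that had at least 2 passing probe sets, 41.5% had passing probe sets in opposite directions. Without the Th1 vector pair 6336 probe sets passed and without the Th1 DN Trpm4 pair 5845.

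Single pairs were read as values with no test. At least 2-fold differences were seen for 81 probe sets in the Th1 siRNA pair, 48 in the Th2 siRNA pair, 48 and 14 in the Th1 pairs of DN Trpm4 at 12 h and 4 h, and 83 and 67 in the Th2 pairs at 12 h and 4 h. In the Th1 siRNA pair the prolyl hydroxylase genes P4ha2 and Egln3 had log2 ratios of 1.02 and 0.90, and Setd4, the cell cycle inhibitor gene Cdkn2a and the Wnt target Axin2 had -1.27, -1.09 and -1.06. In the Th2 siRNA pair Samd10 stood at 1.05, the TNF receptor gene Tnfrsf8 at 0.73 and the ion channel gene Hcn3 at -1.40. In the Th1 pair of DN Trpm4 at 12 h, Micall2, Mdk and the receptor gene Notch2 had 1.20, 1.01 and 1.0 and the actin-binding gene Cttn -0.93. In the Th1 pair at 4 h, Zfp711 had 0.84 and Ccdc90b -2.01. In the Th2 pair at 12 h, Zfp629 and Klf9 had 1.07 and 0.92, and Ugcg, an enzyme of glycolipid synthesis, -1.18.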

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

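The tests of whether Th1 and Th2 cells themselves change differently with time, and both tests of the Trpm4 signal under DN Trpm4, were chosen after the result was seen. The differences between the cell types were picked out by a test of the difference itself, while the cell cycle value within Th1 and the Trpm4 signal under DN Trpm4 were chosen from the values. Single samples far from others could not be tested, with 1 array per group.

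The change from 4 h to 12 h differed between Th1 and Th2 cells for 11253 probe sets. A candidate explanation is 3′ bias, which changed between the Th1 arrays at 4 h and at 12 h and not between the Th2 arrays. The Th1 change correlated across 29467 probe sets with the difference between Th2 siRNA arrays and Th2 retrovirus arrays at 12 h, which also differ in bias and in treatment (r = 0.52, Spearman 0.50), against 0.39 with the Th2 change over time and 0.23 with Th1 minus Th2 siRNA, where bias did not change, so 0.52 need not follow bias alone. Passing probe sets of 41.5% of 2010 genes went in opposite directions, against 6.3% in Th1 minus Th2 at 4 h, where both arrays are biased. Different changes in the cell types stay open and cannot be told apart from it, since 0 of the 2 Th1 pairs of times shared one kind of array.

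Of 3 regroupings of the pairs for this difference 1, the real one, gave as many probe sets (highest other 0), which are too few for a share under 0.05. Named genes with this difference were Ube2s at 5.39, Timm10b at 4.37, Smn1 at 4.34, Tgfb1 at 4.32, Ccl1 at 4.31, Ube2n at 4.01, Ubl5 at 3.97, Lsm2 and Bsg at 3.87, Ubl7 at 3.78, Lag3 at 3.77 and Banf1 at 3.6. In the other direction were Gbp6 at -3.87, Irgm2 at -3.67, Sytl2 at -3.66, Iigp1 at -3.61, Arhgap6 at -3.39, Igtp at -3.34, Grn and Msc at -3.33, Parp14 at -3.31, Cyp51 at -3.30, St8sia4 at -3.11 and Onecut2 at -3.07. Tgfb1, Ube2n and Ubl5 each have another probe set of opposite sign. The spread behind these calls is that between near-duplicate pairs of one cell type. Thy1 differed by 0.73 (adjusted p = 0.0184 in limma), and without the Th1 vector or the Th1 DN Trpm4 pair it did not pass (adjusted p = 0.0854 and 0.185), nor with a pseudocount of 1 (adjusted p = 0.0607), with a range from 0.00326 to 0.185 over the alternatives. Cell cycle genes (median 0.44) and cholesterol synthesis genes (median -1.0) differed as lists, neither with an estimated correlation (adjusted p = 0.879). The cholesterol call ended without the Th2 DN Trpm4 pair (adjusted p = 0.0522).

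With Trpm4 inhibited, the effect in Th1 minus that in Th2 differed for cell cycle genes (median -0.24), cytokine and chemokine genes (0.17) and Th2-associated genes (0.14). With an estimated correlation the call of the cell cycle genes held (adjusted p = 0.0476) and the other 2 did not (0.974). For the cell cycle genes that estimate was -0.0098, so the test made no allowance for genes moving together. With DN Trpm4 alone the medians were -0.20, 0.23 and 0.20, and none held with an estimated correlation (adjusted p = 0.713, 0.923 and 0.923). The cytokine and Th2-associated values rest on the Th2 pair at 4 h, without which they were -0.03 and 0.03, and -0.06 and -0.06 with DN Trpm4 alone.

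Cell cycle genes lower with Trpm4 inhibited in Th1 cells were weighed further. The values argue against one pair of arrays as the whole cause. With a Th1 pair left out, the highest adjusted p of the list was 1.39e-05, in camera at the preset correlation. Against random lists of matched expression, the highest percentile of the list median was 0.02 in the 3 Th1 pairs. This argues against a scaling shift shared by all genes of that expression, and against no other difference between arrays. The random lists make no allowance for genes moving together, so a small difference between 2 arrays can give an extreme percentile. The same list stood at 99.85 in the Th2 siRNA pair, and at 35.14 and 88.96 in the Th2 pairs of DN Trpm4 at 12 h and 4 h. The highest median of the 3 Th1 pairs was -0.10, so inhibition of Trpm4 may lower cell cycle genes in Th1 cells, a hypothesis from the same data. Other differences between the arrays of a pair stay open as well. No cell counts or cycle stages were used here, and the siRNA control differs in Thy1 too.

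The Trpm4 signal under DN Trpm4 stood 2.59 above the vector on the log2 scale in Th1 cells at 12 h, the 1 retrovirus pair without 3′ bias. Bias could hide a construct in the other pairs, whose highest log2 ratio was 0.60, but with 1 unbiased pair this stays open. The difference between the Th1 and Th2 effects was 1.65 (adjusted p = 1 in limma), so a higher level of the construct in Th1 cells stays open as well, and both cannot be told apart.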

How the results depend on the processing

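Tests in subsets of arrays by 3′ bias and on averages of the arrays of each set were chosen after the result was seen and all other alternatives before. Of the values for named genes and lists, 2947 kept direction and side of the threshold, 232 stayed in direction but no longer passed, 13 newly passed and 17 reversed. Of the counts and correlations 157 stayed within their limits and 44 moved. The cause was not tested unless named. In the limma fits every scaling moved the median of all probe sets by under 0.1. Of the single pairs it moved from -0.06 to -0.21 on the deposited values in the untreated pair and from 0.00 to 0.10 median-centred in the Th2 DN Trpm4 pair at 12 h. Fits for Trpm4 over both cell types, in Th1, in Th2, for their difference and for DN Trpm4 gave 0 calls in limma under all alternatives. Low signals near the floor limit every fold.

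Th1 minus Th2 (2884 probe sets) gave 1734 with 1 probe set per gene, where fewer probe sets are tested, and 5161 with no pair block against the paired fit. It gave 1256 without the 12 h pairs, 319 in the untreated and siRNA pairs, 8111 in the 4 h pairs, 271 with the arrays of each set averaged, and 1450 to 2901 leaving out one pair. The cell cycle median (-0.55) was 0.67 in the untreated and siRNA pairs. Trpm4 (-0.07) was 0.00 with a pseudocount of 64 and -0.44 to 0.04 leaving out one pair. On the deposited values 783 were higher and 2338 lower, against 1076 and 1808.

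The 12 h minus 4 h count (592) was 385 median-centred, 351 with a trend, 965 with 1 probe set per gene, 3537 with no pair block, 3248 with array weights, 0 with a pseudocount of 1, 0 to 0 leaving out one pair, 1846 in the Th2 pairs and 0 with the arrays of each set averaged. Of the passing probe sets 90 were higher and 453 lower on the deposited values and 73 and 312 median-centred, against 210 and 382. For 12 h minus 4 h, Th1 effect minus Th2 effect, the count (11253) was 5080 with 1 probe set per gene and 5845 to 12630 leaving out one pair.

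Thy1 with DN Trpm4 (0.05) was -0.02 on the deposited values, -0.03 median-centred, -0.02 with array weights and 0.00 to 0.13 leaving out one pair. Leaving out one pair gave Trpm4 over both cell types (0.29) as -0.17 to 0.49, in Th1 (0.82) as -0.06 to 1.59, both lowest without the Th1 DN Trpm4 pair at 12 h, Thy1 in Th1 (0.39) as -0.08 to 0.68, and Thy1 in the difference (-0.43) as -0.90 to 0.21. Cytokine medians were -0.03 to 0.24 in the difference (0.17), -0.15 to 0.04 with DN Trpm4 (-0.10) and -0.06 to 0.50 in the DN Trpm4 difference (0.23). There the Th2-associated median (0.20) was -0.06 to 0.47, and the count of 0 in limma (976 unadjusted) was 0 to 1, with 1 without the Th2 pair at 12 h. The siRNA count (0 in limma, 3318 unadjusted) was 98 with a trend and 4 with a pseudocount of 64. Leaving out one siRNA pair could not give a test, with no residual degrees of freedom.

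Counts of single pairs at 1.5-fold and 3-fold were 1034 and 3 (Th1 siRNA), 687 and 8 (Th2 siRNA), 678 and 3 (Th1 DN Trpm4 12 h), 85 and 3 (Th1 DN Trpm4 4 h), 1213 and 4 (Th2 DN Trpm4 12 h), 1280 and 4 (Th2 DN Trpm4 4 h, with 102 at 2-fold on the deposited values) and 9582 and 1163 (untreated Th1 minus Th2), by the change of limit.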

Other observations

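The test by swaps of whole sets and the reading of the Th2 pair at 4 h were chosen after the result was seen, and the other tests by splits were planned. In that pair, DN Trpm4 against vector, several lists lay below random lists of matched expression. Cytokine and chemokine genes had a median log2 ratio of -0.50, with 3 of 32 above 0, ribosome biogenesis genes one of -0.40 and T cell activation and NFAT-induced genes one of -0.34. Th2-associated, Th1-associated and unfolded protein genes stood at -0.31, -0.27 and -0.25, all 6 lists at a percentile of 0.01 or lower. The eosinophil growth factor gene Il5 had a ratio of -1.43, the growth factor gene Il3 -1.34, Uhrf2 -1.36 and the retinoic acid binding gene Crabp2 -1.03, while the translation factor gene Eif4g2 had 1.15 and the secretory pathway gene Surf4 1.05. In the Th2 pair at 12 h the cytokine, ribosome biogenesis and activation medians were 0.09, 0.14 and 0.13. The arms of the Th2 pair at 4 h also differed more in 3′ over 5′ signal than those of the other retrovirus pairs for Actb (3.96 with the vector, 4.85 with DN Trpm4) and Tfrc (2.46 and 3.09). These are values of single pairs with no test.

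In the untreated pair 3788 probe sets differed at least 2-fold between Th1 and Th2. Among probe sets above the median of both arrays Zc3h10 had a log2 difference of 5.88, Ifng 5.23, Ccl5 5.14, Gzmc 5.07, Klrk1 5.02 and Il18r1 4.53. Outside that limit Klrd1 stood at 7.02 and Klrc1 at 6.17. On the other side Epas1 had -5.26 within it, the steroid dehydrogenase gene Akr1c18 -5.25, Serpinf1 -5.23, Ecm1 -4.90, Il10 -4.82 and the cytokine gene Lif -4.67, while outside it Penk stood at -8.11, Pth at -6.11 and Cyp11a1 at -5.93. The differences of Il4 (-2.73) and Il5 (-1.76) were the smallest of the 7 pairs in size. Markers of macrophages and dendritic cells had a median of -1.63 in this pair, B cell markers -0.81 (Ighm at -4.36) and markers of CD8 T cells and natural killer cells 1.67.

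Other splits of the arrays were fitted in the same way. For Th1 minus Th2, 1 of 100 random splits and 1 of 64 swaps within pairs, the real one, gave 2884 probe sets, against 1073 and 315 for the highest other. These splits treat the 7 pairs as independent, which excludes chance only on that footing. With the 4 sets of arrays swapped whole, 1 of 8 swaps gave as many (highest other 315, the swap of both siRNA pairs), and 8 are too few for a share under 0.05. For 12 h minus 4 h the random splits can neither exclude chance nor show it. Of 32 splits 3 gave as many as the real 592, the real one among them, the highest being 12521. The others with as many set both Th1 arrays at 12 h against both at 4 h and put a whole Th2 pair on each side. They repeat the time comparison within Th1 cells, where time and kind of array changed together. Within the Th2 arrays, all of 1 kind, 1846 passed, from 2 near-duplicate pairs with 1 residual degree of freedom. Of 8 swaps within pairs 1 gave as many (highest other 0), and 8 are too few for a share under 0.05.

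With Trpm4 inhibited the real count in limma was 0 in each fit (1733 at an unadjusted p under 0.05 over both cell types), so every split gives as many by construction and these splits decide nothing. Over both cell types 99 of 99 random splits gave as many (highest other 2) and 32 of 32 swaps did (highest other 0), and with DN Trpm4 32 of 32 random splits did (highest other 0). The other fits had 10 of 10 splits and 4 of 4 swaps in Th1 (highest other 2 and 0), 10 of 10 and 4 of 4 in Th2 (1 and 0) and 10 of 10 regroupings for the difference (0). With DN Trpm4 they had 8 of 8 swaps (0), and 3 of 3 regroupings for its difference (0).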
